A study of Mus musculus with 2 samples.

How the data were processed

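The series measured RNA from postnatal day 0 mouse skeletal muscle in 2 libraries of 13 pg total RNA each, from a portion of tissue of 1 pup per library. Per the labels' protocols, RNA was extracted with the mirVana kit, RNA above a size of 200 was used, libraries followed a SmartSeq protocol, which amplifies full-length cDNA, and spike-in RNAs were added. Both libraries belong to 1 group and carry the biological replicate numbers 1 and 2 of the labels. Sex was not collected. Per the labels both libraries come from pups with separate tissue records but the same donor entry. The spread between them can hold differences between animals, tissue portions and libraries, which cannot be told apart.

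For each library the authors deposited a table of genes and a table of transcripts. Expected counts, which are estimated reads per gene that need not be whole, were deposited by the authors without normalization, and per the file headers the columns are those of RSEM with posterior means. The deposited TPM values are length-adjusted and scaled by the authors to one fixed sum over all rows of a file, spike-ins included. The deposited FPKM values are fragments per effective length and library total. Per the descriptions deposited with the files, reads were assigned to mm10 with the GENCODE M4 annotation. The aligner and its version are not given in the sources used here, nor is whether strand was used, so reads of a gene and of an antisense gene, such as Xist and Tsix, may not be told apart. Effective length was the length minus 99 in most rows.

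The gene tables held 69691 rows, of which 43346 were genes, 96 were spike-ins of the ERCC set, 1 was the phiX control and 26248 were short numbered rows. Numbered rows held 0 expected counts in replicate 1 and 182 in replicate 2, phiX held 0 in both, and both kinds were left out. The transcript tables held 129984 rows. Symbols, gene types and coordinates came from GENCODE M21 on GRCm38, the assembly also called mm10, matched by identifier without version. This gave a symbol to 42462 genes and none to 884. Totals were 32103374 expected counts in replicate 1 and 38977618 in replicate 2, of which 1670852 and 974277 were on spike-ins. At least 5 reads were seen on 33 and 27 spike-ins. There are no molecular identifiers, so reads after amplification are not separate molecules, and all intervals and limits cover counting error only. A count of 0 was taken to allow up to 3 counts.

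A gene was called detected at a TPM of at least 1 with at least 5 expected counts. The overlap of independent lists was the product of both numbers divided by the genes in the file. Log values used log2(TPM + 1). Myosin shares were taken of the summed TPM of 10 sarcomeric heavy chains. A pair ratio was said to exceed the spread when its sign was the same in both libraries and its mean exceeded 2 SD. For gene lists between libraries, log2 ratios were centred on the median gene, members under 5 counts in both libraries were left out, and a list's median was ranked among 10000 random lists of the same size drawn from the same deciles of mean level. Lists with under 3 usable members, cartilage and bone and epidermis, were not compared. After the list medians were seen, members of the fast fibre list were set against those of 5 other lists with a two-sided permutation test of the difference of medians, exact for lists of up to 10 members and otherwise with 100000 resamples. Members of a list are not replicates. Genes with at least 10 counts in both libraries were set against the largest spike-in ratio of their bin of mean count, with at least 5 spike-ins per bin. Spike-ins under 10 counts in a library were left out of this limit. Shares have Wilson or exact binomial intervals and reads have exact Poisson intervals, at 95%. Expected counts were rounded to whole numbers where they were drawn down to a lower depth. edgeR 4.0.16 in R 4.3.3 served only to compute TMM scaling factors for an alternative scaling. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

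The calculation of genes beyond the spike-in spread was tested on simulated counts of 43346 genes for replicate 1 against replicate 2. It called 99% of 100 genes changed by a log2 of 3 and all of 100 changed by 6, and 4.18% of 7770 unchanged genes. The simulation gave genes and spike-ins the same SD of 0.72 log2 at every count and no loss of molecules. In the data the SD of spike-ins was 0.96 at 1000 to 10000 counts and 0.49 above. The 4.18% is therefore not an error rate for the calls in the data. Of 40 lists of unchanged genes, 2 lay outside the central 95%.

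Lists, gene naming, most alternatives and the tests of the results were fixed before the data were examined, except the permutation tests between lists. The fit on transcript length and GC content and the tests of explanations in the closing section were also chosen afterwards. The 24 lists were myosin heavy chains, fast fibre, slow fibre, heart and fetal sarcomere, sarcomere core, acetylcholine receptor and synapse, excitation-contraction coupling, myogenic regulators, proliferation, glycolysis, nuclear respiratory chain, imprinted growth genes, immediate early and heat shock, fibroblast, tendon, cartilage and bone, endothelium, mural and smooth muscle, erythroid, macrophage, other leukocytes, Schwann cell, adipocyte and epidermis. Of 245 members, 244 had a row, and Ahsp had none under its symbol. The text names all heavy chains, both members of each pair, per list up to 4 members of highest mean TPM among those detected in both libraries, the 10 highest genes, the 5 genes furthest beyond the spike-ins each way, the sex-linked genes, and genes whose leading transcript differed plus the 5 of highest count. Other named genes are said to be chosen after their values were seen. Alternatives covered the pseudocount, detection thresholds, count minimums, FPKM, expected counts and posterior mean TPM in place of TPM, centring on spike-ins, drawing down the deeper library and leaving out each library.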

Results

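RNA was measured in skeletal muscle of newborn mice of the B6NCrl strain, a C57BL/6N line, on postnatal day 0. Each of 2 libraries was made from 13 pg of total RNA from a tissue portion of 1 pup, an amount the labels equate with 1 cell, and not from a single isolated cell. The labels call the libraries biological replicates 1 and 2 of the same tissue. They name 1 pup for each library and separate tissue records, but the same donor entry for both. The replicates form 1 group, so the design implies no comparison between conditions and instead asks what newborn muscle RNA looked like at this input and how far both libraries gave the same picture. Replicate 1 held 32103374 expected counts and replicate 2 held 38977618. Values are in TPM, the length-adjusted share of transcripts, given as mean with the SD over n = 2 unless stated otherwise, and positions are on GRCm38. An exact two-sided test of 2 unpaired values against 2 cannot go below p = 0.333. Genes of a pair were measured in the same libraries, and the libraries stand 1 against 1, so even less can be tested here. Differences were therefore set against the SD and not against a p-value. Passing 2 SD with n = 2 is a description and not a test of significance.

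Contractile RNA held the highest places in both libraries. The myosin heavy chain, fast fibre, slow fibre, heart and fetal sarcomere and sarcomere core lists together held 19.9 ± 2.59% of all TPM. Acta1, the skeletal alpha-actin of the thin filament (chromosome 8, 123891769 to 123894751), was the highest gene at 63145 ± 1968. It was followed by Myl1, the fast essential myosin light chain, at 24977 ± 3492, and by Tnnc2, the fast troponin C, at 19771 ± 867. Ckm, the muscle creatine kinase, reached 13983 ± 1904. Mylpf, the fast regulatory myosin light chain, reached 11519 ± 6074, and Tnnt3, the fast troponin T, reached 10409 ± 3869. The remaining places among the 10 highest genes were held by mt-Atp6 at 13285 ± 1473 and mt-Atp8 at 9448 ± 511, subunits of the ATP synthase encoded in mitochondrial DNA, by the pseudogene Gm28437 at 13437 ± 2315 and by Gm42418 at 10179 ± 10050. Gm28437 lies in a copy of mitochondrial sequence on chromosome 1 (24613189 to 24613971), so its reads and those of the mitochondrial genes cannot be told apart with certainty. Gm42418, annotated as a long noncoding RNA on chromosome 17 (39846958 to 39848788), was 17285 in replicate 1 and 3073 in replicate 2.

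The 10 highest genes took 18.7% of TPM in replicate 1 and 19.3% in replicate 2. Mitochondrial genes took 5.88 ± 0.180% and the 6 detected pseudogenes of the mitochondrial copy on chromosome 1 (24612407 to 24616197), which can share their reads, a further 3.04 ± 0.0972%. Ribosomal protein genes took 5.15 ± 1.66% and haemoglobin genes 0.346 ± 0.0238%. Spike-in RNAs, added in known amounts during preparation, took 9.44% in replicate 1 and 4.54% in replicate 2. Computed from expected counts, the shares were lower, at 14.4% for the 10 highest genes, 3.59% for mitochondrial genes, 2.42% for ribosomal protein genes, 0.134% for haemoglobin genes, and 3.85 ± 1.91% for spike-ins, against a mean of 6.99% by TPM.

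Perinatal myosin was the main heavy chain of both libraries. Myh8, the perinatal myosin heavy chain, took 86.2 ± 4.43% of the summed TPM of the 10 sarcomeric heavy chains, and Myh3, the embryonic form, took 9.93 ± 3.23%. Myh7, the slow and cardiac beta form, took 2.43 ± 1.70%. Adult fast forms were low, with Myh4 (type IIb) at 0.712 ± 0.258% and Myh1 (type IIx) at 0.598 ± 0.112%, while Myh2 (type IIa) had 0.280 ± 0.0990 TPM. Myh8 (67277124 to 67308634), Myh3 (67078300 to 67102291), Myh1, Myh2, Myh4 and Myh13 lie in a cluster on chromosome 11. Myh13, the extraocular form, had 0.130 TPM in replicate 1 and 8.97 in replicate 2, and Myh6, the cardiac alpha form, had 0.140 ± 0.0566. Myh7b and Myh15 had 0 counts in both libraries, and a count of 0 allows up to 3 counts. The order Myh8, Myh3, Myh7 held in each library, with Myh8 at 83.1% and 89.4%, Myh3 at 12.2% and 7.65%, and Myh7 at 3.63% and 1.22%. Heavy chain genes share sequence, so reads of the low members may be split in error.

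Fast, skeletal, muscle or perinatal members exceeded their slow, cardiac, general or embryonic partners in most of 13 gene pairs. The pairs were fixed before the data were examined. The log2 ratio had 1 sign in both libraries and a mean over 2 SD in 10 pairs. Atp2a1, the fast calcium pump of the sarcoplasmic reticulum, exceeded Atp2a2, the slow and cardiac pump, with a log2 ratio of Atp2a2 to Atp2a1 of −6.83 ± 0.58. The troponins gave −4.86 ± 0.19 for Tnnc1 over Tnnc2, −4.34 ± 0.06 for Tnnt1 over Tnnt3 and −2.75 ± 0.85 for Tnni1 over Tnni2, with the slow member first. Myl4, an atrial and fetal light chain, stood at −5.14 ± 0.11 against Myl1, and Actc1, the cardiac actin, at −3.17 ± 0.48 against Acta1. Myh7 over Myh8 gave −5.34 ± 1.18 and Myh3 over Myh8 gave −3.15 ± 0.55. Neither of these pairs holds an adult fast form, and Myh7 stood above Myh4 and Myh1 in both libraries. Among metabolic genes, the general enolase Eno1 stood at −2.07 ± 0.14 against the muscle form Eno3, and Cox6a1 at −0.85 ± 0.28 against its heart and muscle form Cox6a2.

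Remaining pairs did not exceed 2 SD. Cox8a over Cox8b gave −0.54 ± 0.67 and Cox7a2 over Cox7a1 gave 0.38 ± 0.47. The fetal acetylcholine receptor subunit Chrng against the adult subunit Chrne gave −1.60 in replicate 1 and 5.62 in replicate 2. Chrne had 1587 reads in replicate 1 and 0 in replicate 2, and Chrng had 948 and 3346, so this pair had no common direction. Ratios are of TPM + 1, which understates the difference where a gene is low.

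**Figure D1:**
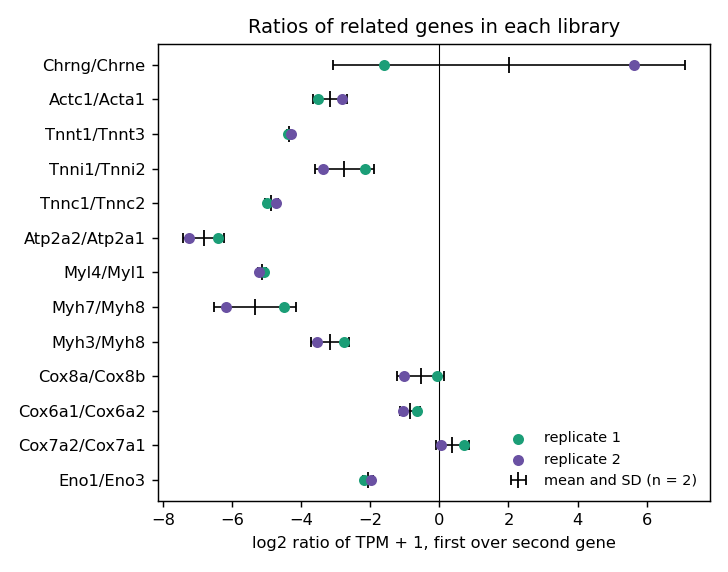
Log2 ratio of TPM + 1 (x axis, no unit) for each of 13 gene pairs (y axis, first over second gene), with 1 point per library and the mean and SD over n = 2. Ratios lie left of 0 in both libraries for the 10 pairs past 2 SD, and the points of Chrng/Chrne lie on opposite sides of 0.

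Fibre, energy and imprinted genes were found in full. All 10 fast fibre genes, 9 slow fibre genes, 12 glycolysis genes, 10 nuclear respiratory chain genes and 12 imprinted growth genes were detected in both libraries, at a TPM of at least 1 and 5 expected counts. Slow fibre genes were led by Mybpc1, slow myosin-binding protein C, at 1879 ± 58.3, Casq2, the cardiac and slow calsequestrin, at 1522 ± 293, Tnni1 at 996 ± 211 and Tnnc1 at 685 ± 121. Glycolysis was led by aldolase Aldoa at 9111 ± 1038, Eno3 at 5639 ± 1079, Gapdh at 4741 ± 1879 and the muscle phosphoglycerate mutase Pgam2 at 3371 ± 663. The respiratory list was led by the ATP synthase subunit Atp5b at 3437 ± 1914, Ndufa4 at 1243 ± 498, Cox6a2 at 1140 ± 370 and Cox8b at 931 ± 834. Imprinted genes of fetal growth were abundant, with the noncoding RNA H19 at 3356 ± 208, Meg3 at 2387 ± 1279, the growth factor Igf2 at 1940 ± 408 and Mest at 915 ± 92.8.

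Sarcomere core genes were found in both libraries for 15 of 16 members, with Tpm1 at 9435 ± 1599 and Tpm2 at 6788 ± 2740 next after Acta1 and Ckm. The exception, named after its values were seen, was Mb, the oxygen-binding protein myoglobin, with 0 reads in replicate 1 and 115 in replicate 2. The heart and fetal list gave 3 of 8 members, Actc1 at 7196 ± 2157, Myl4 at 702 ± 43.8 and the cardiac troponin T gene Tnnt2 at 305 ± 211.

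Neuromuscular and triad genes were present at lower levels. The acetylcholine receptor and synapse list had 7 of 10 members in both libraries, including the receptor subunits Chrnb1 at 95.1 ± 40.0 and Chrna1 at 53.6 ± 35.6, the clustering protein gene Rapsn at 94.8 ± 26.8 and Dok7 at 43.0 ± 38.5. Excitation-contraction coupling had 8 of 12, led by the calcium channel subunit Cacng1 at 634 ± 61.7, Srl at 620 ± 469, triadin (Trdn) at 113 ± 16.9 and Jsrp1 at 55.4 ± 32.4. Myogenic regulators had 7 of 12. Mymk, the myoblast fusion protein, stood at 330 ± 15.1, with the transcription factors Myog at 233 ± 45.1, Myf6 at 201 ± 91.0 and Mef2c at 143 ± 31.4. Proliferation genes also had 7 of 12 in both, with Cdk1 at 177 ± 109, Pcna at 72.8 ± 56.9, Top2a at 56.7 ± 52.1 and Birc5 at 46.4 ± 58.0. Immediate early and heat shock genes, read as signs of handling stress, had 1 of 12 in both, Atf3 at 2.62 ± 0.325.

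Markers of other cell types of muscle were led by connective tissue. Fibroblast markers were found in both libraries for 10 of 11 genes, with the collagens Col3a1 at 2158 ± 737, Col1a1 at 1307 ± 739 and Col1a2 at 795 ± 288 and the matrix protein Postn at 1082 ± 3.48. Endothelium gave 6 of 10, with Egfl7 at 175 ± 49.3, Esam at 81.6 ± 10.1, the receptor Tek at 15.2 ± 18.1 and Tie1 at 13.3 ± 11.7. Mural and smooth muscle markers gave 3 of 8, with Acta2 at 403 ± 119, Kcnj8 at 53.6 ± 48.9 and Rgs5 at 42.3 ± 15.2. Tendon gave 2 of 7, Col12a1 at 53.5 ± 49.3 and Tnmd at 11.2 ± 11.9. Schwann cell markers gave 2 of 8, Ngfr at 10.3 ± 4.16 and Erbb3 at 4.44 ± 3.49.

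Blood, immune and fat markers were also measured. All 4 erythroid markers found in both, of 10 listed, were globins, with Hba-a2 at 1384 ± 46.5, Hbb-bs at 950 ± 58.2, Hba-a1 at 694 ± 172 and Hbb-bt at 432 ± 171. The split of reads between near-identical globin copies is uncertain. Macrophage markers gave 5 of 10, with the complement genes C1qb at 162 ± 166 and C1qa at 153 ± 15.7, Lyz2 at 111 ± 99.6 and Mrc1 at 25.3 ± 25.5. Of the other leukocyte list, 3 of 10 were found in both, and these were the mast cell protease genes Cma1 at 555 ± 143, Cpa3 at 459 ± 264 and Mcpt4 at 80.7 ± 51.2. Adipocyte markers gave 5 of 9, with the fatty acid carrier Fabp4 at 797 ± 113, adipsin (Cfd) at 555 ± 729, adiponectin (Adipoq) at 226 ± 201 and the lipase Lpl at 190 ± 11.2. Cartilage and bone gave 0 of 9 and epidermis 0 of 8. Over the 24 lists, 146 of 244 members with a row in the files were detected in both libraries, and a median is moved by dropout where a list has few detected members.

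Genes of high level were found in both libraries and genes of lower level often in 1 only. Above 300 TPM in replicate 1, where Acta1, Myh8, H19 and Col3a1 lie, 454 of 454 genes were also detected in replicate 2, and in the other direction 463 of 464. At 30 to 100 TPM, the range that holds Chrnb1 and Rapsn in at least 1 library, 69.7% (Wilson 95% interval 67.7 to 71.5) of genes of replicate 1 were found in replicate 2, and 64.9% (62.9 to 66.9) the other way. At 1 to 3 TPM the shares were 50.2% (46.4 to 54.0) and 42.9% (39.1 to 46.9). In all, 6350 genes were detected in replicate 1 and 6949 in replicate 2. Of these, 4356 were found in both, against 1018 for independent lists, 1994 in replicate 1 only and 2593 in replicate 2 only. Drawing replicate 2 down to the depth of replicate 1 left 4353 in both.

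**Figure D2:**
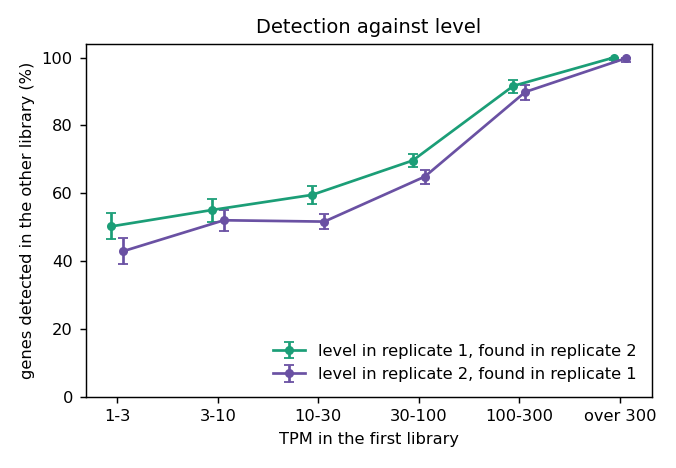
Share of genes detected in the other library (y axis, percent, at least 1 TPM and 5 expected counts) against the TPM in the first library (x axis, bins of TPM), for each direction, with Wilson 95% intervals for counting error. Shares go from 50.2% and 42.9% at 1 to 3 TPM to 100% and 99.8% over 300 TPM.

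Levels of some high genes were close between libraries, at 1.05-fold for Acta1, 1.22-fold for Myl1 and 1.29-fold for Myh8. Others differed more, with Mylpf 2.19-fold and Tnni2 3.11-fold higher in replicate 2 and Gm42418 5.63-fold higher in replicate 1. Across the 8943 genes detected in at least 1 library, log2(TPM + 1) gave Pearson r = 0.332 and Spearman rho = 0.296, across genes, which are not independent replicates. Among 4872 genes with at least 10 expected counts in both libraries, r was 0.726 and rho was 0.712. Over 35 spike-ins, r was 0.757 and rho was 0.851, and over the 25 spike-ins with at least 10 counts in both, r was 0.961. With a pseudocount of 0.1, r over genes was 0.122.

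**Figure D3:**
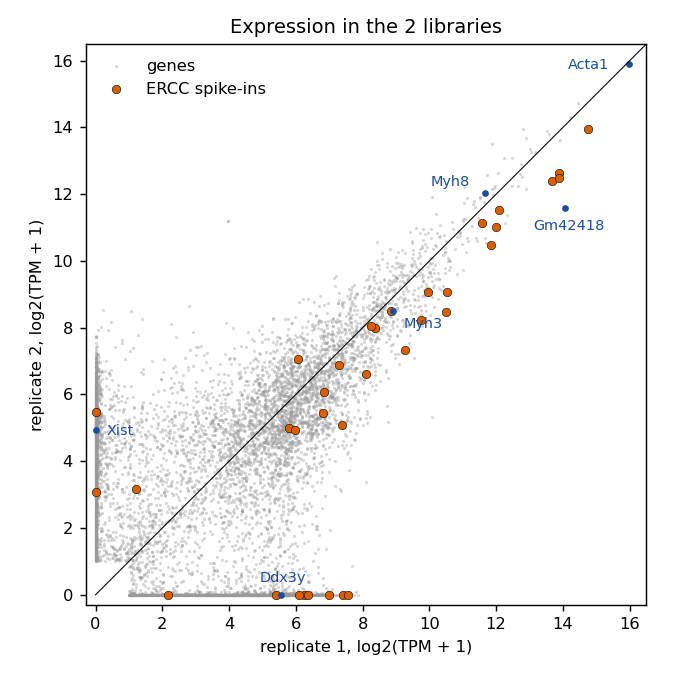
Log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), with 1 grey point per gene detected in at least 1 library and carrying a symbol (8892 genes), spike-ins in orange and named genes in blue, and the line of equal values. Acta1 and Myh8 lie near the line, Gm42418 lies below it, and many genes lie on an axis because they were found in 1 library only.

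Fast fibre and nuclear respiratory chain genes were higher in replicate 2, and adipocyte markers in replicate 1, relative to the median gene. The fast fibre list had a median log2 ratio of replicate 1 to replicate 2 of −0.95, with 0 of 10 members higher in replicate 1. Tnni2, the fast troponin I, was 3.11-fold higher in replicate 2, Mylpf 2.19-fold, Tnnt3 1.71-fold and Tnnc2 1.06-fold. The respiratory list had a median of −1.01 and all 10 members higher in replicate 2, with Cox8b 4.46-fold, Atp5b 2.30-fold, Ndufa4 1.79-fold and Cox6a2 1.59-fold higher there. The adipocyte list had a median of 1.17 with 5 of 6 members higher in replicate 1, where Cfd was 27.2-fold, Adipoq 4.42-fold, Fabp4 1.22-fold and Lpl 1.09-fold higher. The exception, named after its values were seen, was Plin1, the lipid droplet protein perilipin, with 8 reads in replicate 1 and 1060 in replicate 2.

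Among 10000 random lists of the same size and deciles of level, these medians lay at percentiles 0.45, 0.35 and 99.1. Matching was coarse for the highest genes, since their decile also held lower genes. The SD of gene log2 ratios was 2.25 at mean counts of 1000 to 10000 and 0.87 above 10000. Of 22 lists compared, 3 lay outside the central 95% and 1.1 would by chance, and 9.48% of sets of 22 independent random lists would have as many outside. The other 19 lay inside. Nearest to the edge were heart and fetal sarcomere at −1.12 (percentile 4.18), with 0 of 4 members higher in replicate 1, and other leukocytes at 1.20 (percentile 96.8), with 3 of 3. Slow fibre lay at −0.40, sarcomere core at −0.39, glycolysis at −0.32, erythroid genes at −0.26, imprinted growth genes at −0.13, macrophage at 0.11, fibroblast at 0.48 and endothelium at 1.60. In tests chosen after the list medians were seen, fast fibre genes against sarcomere core genes differed by −0.56 in the median (two-sided permutation p = 0.0717, Benjamini-Hochberg adjusted p = 0.120 over the 5 lists compared with it), and against slow fibre genes by −0.54 (exact permutation p = 0.0369, adjusted p = 0.0923). Against glycolysis the difference was −0.63 (permutation p = 0.0246, adjusted p = 0.0923), against excitation-contraction coupling −0.26 (p = 0.730, adjusted p = 0.883, permutation) and against the respiratory list 0.06 (p = 0.883, adjusted p = 0.883, exact permutation). None of the 5 passed 0.05 after adjustment. The percentiles describe 2 libraries of 1 group with no replicate check. Centring on the spike-ins in place of the median gene lowers each list median by 0.94 log2, which leaves the adipocyte median at 0.23, turns 4 of the 7 lists above 0, to −0.46 for fibroblast, −0.62 for tendon, −0.82 for immediate early and heat shock and −0.84 for macrophage, and can only lower lists that already lie below 0.

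**Figure D4:**
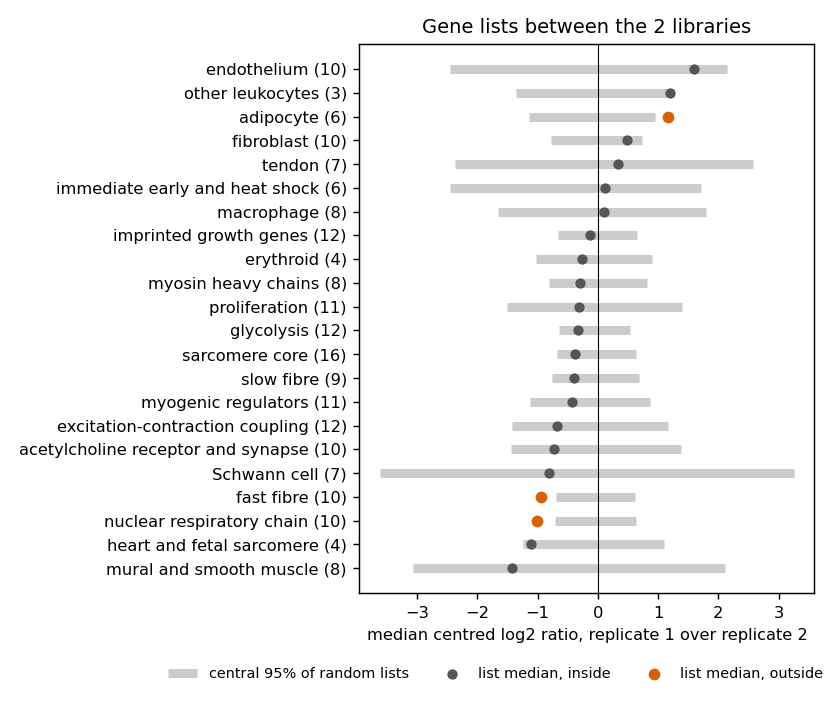
Median centred log2 ratio of replicate 1 to replicate 2 (x axis) for 22 gene lists (y axis, members used in brackets). Grey bars give the central 95% of 10000 random lists of the same size and deciles of level. Fast fibre (−0.95), nuclear respiratory chain (−1.01) and adipocyte (1.17) lie outside their bars. Centred on the spike-ins, each median lies 0.94 lower, so that fibroblast, tendon, macrophage and immediate early and heat shock change sign.

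Single genes differed between libraries by more than the spike-ins with at least 10 counts in both did. Among genes with at least 10 counts in each library and a mean over 1000, the largest differences toward replicate 1 were Gpam, an acyltransferase of lipid synthesis, with 5486 reads against 10, Washc5 with 5639 against 15, the cytokine-signalling inhibitor Cish with 3226 against 10, Tcof1 with 3880 against 13 and Xylt2 with 2730 against 11. Toward replicate 2 they were the transcription factors Tcf12 with 6215 reads against 11 and Stat5b with 3986 against 10, the calcineurin subunit Ppp3r1 with 7570 against 10, the metallothionein Mt2 with 5161 against 12 and Txndc17 with 4696 against 11. The centred log2 ratios of these genes ran from 9.34 for Gpam to −10.23 for Tcf12. With 10 to 15 reads in the lower library, each ratio is imprecise, and genes with fewer reads in a library, which can differ more, were not ranked.

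Among 3584 genes with a mean over 1000 counts and at least 10 in each library, 375 were higher in replicate 1 and 400 in replicate 2 by more than the largest spike-in ratio, 1.97 log2 or 3.93-fold, which together are 21.6%. Lower count bins held under 5 spike-ins and gave no call. Only spike-ins with at least 10 counts in each library set the limit. Of spike-ins with at least 1000 reads, 4 of 27 in replicate 1 had under 5 in replicate 2, and 0 of 21 the other way. These lost spike-ins set no limit, so the 21.6% is beyond the spike-ins kept in both libraries only. The SD of the log2 ratio was 2.12 over genes and 0.72 over 23 spike-ins, but the genes had a median of 3061 counts and the spike-ins 13399. In narrower bins chosen after the data were examined, the SDs were 2.25 and 0.96 at 1000 to 10000 counts, and 0.87 and 0.49 above 10000. Above 10000 the largest spike-in ratio was 1.06 log2, and by this lower limit 39 of 454 genes were higher in replicate 1 and 51 in replicate 2. At 1000 to 10000 counts the limit stayed at 1.97, with 369 and 395 of 3130 genes beyond it. With genes and spike-ins both centred on the spike-in median, 212 genes were higher in replicate 1 and 804 in replicate 2, so the balance of directions rests on the scaling.

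The same transcript led in both libraries for 16 of 18 muscle genes with at least 50 counts in each, of 20 listed for their splice forms. One of the 16, Pdlim3, named after its values were seen, has 1 transcript in the files, so its agreement was fixed. Myl1 was led by transcript Myl1-202 at 74.1% and 75.7% of its counts in replicates 1 and 2, Tpm1 by Tpm1-205 at 97.2% and 95.9%, and Tpm2 by Tpm2-202 at 68.1% and 70.1%. Titin (Ttn) was led by Ttn-205 at 42.7% and 41.8%, and Tnnt3 by Tnnt3-215 at 27.2% and 28.6%. By transcript TPM another transcript led Ttn in both libraries, at 21.6% and 41.6%, so its leader rests on the measure. The exceptions were Tnnt1, led by Tnnt1-203 at 54.3% in replicate 1 and by Tnnt1-206 at 30.5% in replicate 2, and nebulin (Neb), led by Neb-203 at 42.6% and by Neb-202 at 37.6%. By transcript TPM, Neb had the same leader in both libraries and Mef2c, named after its values were seen, did not, so that 16 genes again had the same leader. The shares come from the authors' model of reads that fit several transcripts.

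Sex-linked RNAs differed between the libraries. Xist, the noncoding RNA of X inactivation (chromosome X, 103460366 to 103483254), had 2 reads in replicate 1 (Poisson 95% interval 0.242 to 7.22) and 16463 in replicate 2 (16213 to 16716), where it stood at 29.8 TPM. Ddx3y, a Y-linked RNA helicase (chromosome Y, 1260771 to 1286629), had 2137 reads in replicate 1 (2047 to 2230) and 0 in replicate 2. Uty had 488 reads in replicate 1 (446 to 533) and 1 in replicate 2. Kdm5d had 1 and 0 reads, and Eif2s3y had 0 in both. The labels state that sex was not collected. Intervals throughout cover counting error only, since reads after amplification are not separate molecules.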

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

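The permutation tests between lists, the count bins split at 10000, the detection minimum of 100 counts, the fit on transcript length and GC content, the centring of list medians on spike-ins and the posterior mean TPM of sex-linked genes were chosen after the data were examined. Of 271 alternative values, 239 stayed within the spread or kept their direction and side of the threshold. Part of these were fixed in advance and say nothing of robustness. With 2 libraries, leaving 1 out moves a mean share by less than its SD. Pairs past 2 SD have 1 sign in both libraries, and pairs within 2 SD were not counted as reversed. A pseudocount cannot change Spearman rho, and FPKM cannot change myosin shares within a library. List medians changed direction when centred on the spike-ins for fibroblast (−0.46), tendon (−0.62), immediate early and heat shock (−0.82) and macrophage (−0.84), as a shift of 0.94 applied to every list, which could turn only the 7 lists above 0. Among pairs within 2 SD, Cox8a over Cox8b went to 0.22 with expected counts and Chrng over Chrne to −1.60 without replicate 2. With expected counts in place of TPM, mitochondrial genes took 3.59%, the 10 highest genes 14.4%, ribosomal protein genes 2.42% and haemoglobin genes 0.134%, as the construction of TPM by length implies. Detection with 1 library left out ranged from 6350 to 6949 genes, since a lone library needs no overlap. Pearson r was 0.122 with a pseudocount of 0.1, 0.726 over genes with 10 counts in both (rho 0.712), 0.718 over all genes (rho 0.655) and 0.225 from CPM. The sets of 10 counts and of all genes differ from the main set by construction; for the pseudocount and CPM the cause was not tested. Counting any TPM above 0 as found raised the shares from replicate 1 to 66.4% at 1 to 3 TPM, 65.5% at 3 to 10, 68.7% at 10 to 30, 76.4% at 30 to 100 and 94.1% at 100 to 300, and those from replicate 2 to 63.7%, 68.1%, 66.1%, 75.2%, 94.6% and, over 300 TPM, 100%. Centring genes and spike-ins on the spike-in median gave 212 genes higher in replicate 1 and 804 in replicate 2. Cox7a2 over Cox7a1 passed 2 SD with expected counts, at 1.68, and other leukocytes left the random range after the length and GC fit, at 1.39; the cause was not tested. Median TPM of the synapse list (33.5) and of imprinted genes (263) moved when TPM was rescaled without spike-ins and mitochondrial genes. No paired analysis was possible because there is 1 group. The gap in depth hardly moved detection, since drawing replicate 2 down left 4353 genes in both against 4356.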

Other observations

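Genes of high level outside the fixed lists, chosen after their values were seen, added further muscle RNAs. Sln, which encodes sarcolipin, an inhibitor of the calcium pump, stood at 5311 ± 1496 TPM (SD, n = 2), Itm2a, a membrane protein gene of differentiating muscle and cartilage, at 3917 ± 134, and Car3, the muscle carbonic anhydrase, at 3595 ± 1869. The nuclear noncoding RNA Malat1 stood at 4451 ± 638. The copies Rn7s1 and Rn7s2 of the signal recognition particle RNA, on chromosome 12, had 14.6 TPM each in replicate 1 and 2357 each in replicate 2, and their reads are split evenly between the copies. Gm42418 went the other way, at 17285 and 3073 TPM.

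All tests here were chosen after the data were examined, and all but the fit on length and GC content after the values they measure were seen. A first pattern is that 2216 genes had at least 1000 reads in one library and under 5 in the other. Depth is argued against, since 41.5% of them (920) were missing from replicate 2, the deeper library. The others would keep at least 825 reads when scaled to the total of replicate 1. The minimum of 1000 reads and the library totals fix that number, so it could not have come out low. Few molecules of each RNA in 13 pg may account for RNAs with reads in replicate 1 only, since 4 of 13 spike-ins of 1000 to 10000 reads there, which carry no difference between animals, were lost too (30.8%, exact 95% interval 9.09 to 61.4), against 24.6% of genes. For RNAs with reads in replicate 2, few molecules stay open, since 0 of 9 spike-ins were lost (0%, upper limit 33.6%) against 31.0% of genes. Spike-ins took 9.44% of TPM in replicate 1 and 4.54% in replicate 2, which by itself favours their loss from replicate 2. The split of spike-in losses by direction therefore cannot be told apart from the amount of spike-in in each library. Genes active in one animal only stay open, because the pooled share of genes lost, 28.0%, exceeded that of spike-ins, 18.2%, by 9.79 percentage points with an interval from −10.57 to 20.7, and animal and library cannot be told apart.

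A second pattern is Xist in replicate 2 and Y-linked RNA in replicate 1. Reads shared with the X-linked copies are argued against, since Ddx3x had 1406 and 3471 reads and would have brought 5276 Ddx3y reads to replicate 2, where there were 0. Few molecules could account only for RNAs missing from a library, not for Xist or Y-linked RNA being present in the other. The shares of autosomal genes lost at the TPM of Xist (39.9%), Ddx3y (30.3%) and Uty (37.4%) have a product of 0.0451. At like reads, which favour long RNAs such as Xist, the product is 0.000788. Both products concern absence alone, so they cannot decide on the pattern as a whole. A candidate explanation is that the pups differed in sex, which the labels do not record and which was not tested. If so, sex goes with replicate in every difference between these libraries.

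Another pattern is the higher level of fast fibre genes in replicate 2. Length and GC content are argued against as its whole cause, since after the fit, which took up 0.964% of the variance, the list lay at percentile 0.27. More muscle fibre in the portion of replicate 2 cannot be told apart from a change of some muscle genes, because the sarcomere core list was 0.56 log2 nearer to 0 than the fast list (permutation p = 0.0717). Fast genes were not alone in the shift, since the respiratory list differed from them by only 0.06 log2 (exact permutation p = 0.883). Few molecules stay open, because the random lists come from the same 2 libraries and hold any difference between portions too. Of these lists 1.07% lay as far out, but with 22 lists compared, 21.1% of such sets would hold at least 1 as far. That share tells how often a list reaches such a median and not why. The deciles also hold genes far below most fast fibre genes, where ratios spread wider, so both shares depend on this matching. After the same fit the respiratory list lay at percentile 1.04 and the adipocyte list at 99.5.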
